A study of Mus musculus with 9 samples.

How the data were processed

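RNA of 9 libraries was measured, 3 for each of the WT, DKO and TKO genotypes. Libraries were made with a stranded mRNA kit that marks the second strand with dUTP and were sequenced as single-end reads of 50 nt, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19.1.403, STAR 2.7.9a and Partek, whose version is not given in the sources used here. They name both GRCm39 and mm10 as genome builds, and neither build's role, the annotation, nor the use of strand in counting is given in the sources used here.

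The deposited count table holds estimated counts per Ensembl gene for all libraries. Of its values above 0, 45.4% differ from a whole number by over 0.000001, and the reason is not given in the sources used here. They were rounded to whole numbers here before any count test. A second deposited table holds CPM. All 54052 of its genes match the count table scaled to CPM by the library total, with 0.0001 added to each count, within 0.5%, and the 2639 genes without a symbol are the ones it leaves out. The count table was the basis of all main results, and the deposited CPM table entered an alternative test only. The count table lists 56691 genes, of which 30693 had any count. Genes were identified by the deposited Ensembl identifiers and symbols. A reference annotation of another build (GENCODE M21 on GRCm38.p6) was used only for which genes neighbour each other, and 16439 of the tested genes (98.2%) were found in it. No coordinates are given, because the role of the builds is unknown.

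Library totals ranged from 31311599 to 38675797 estimated counts, which leaves genes under 0.1 CPM with few counts per library. Where a genotype had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the genotype's libraries. Where it had 1 to 3 counts, the ratio of summed counts is given with an exact Poisson interval at 95%. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

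Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes passing edgeR's default expression filter (16746) were scaled by TMM factors, and a quasi-likelihood model with a coefficient per genotype was fitted to all 9 libraries. The common biological coefficient of variation was 0.0491. A gene was called higher, lower, risen or fallen at a Benjamini-Hochberg adjusted p under 0.05 together with a fold of at least 2. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values were scaled by TMM factors, and means have SDs over 3 libraries. The comparisons were TKO against WT, DKO against WT and TKO against DKO. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 37 lists with at least 3 tested members. Camera was also run with an estimated correlation, and fry was run beside it.

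The samples' groups, the tests, the 38 gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined. Lists covered helper T cell programs, calcium and NFAT signalling, metabolism, growth, stress, other cell types, RNA quality and a sex-linked check. Of the tested members, 16 of 33 calcineurin-NFAT genes, 13 of 25 Th17 core genes and 15 of 22 pathogenic Th17 genes also belong to another list. Of the other cell types' tested markers, WT libraries held 2 of 10 macrophage, monocyte and neutrophil markers, 0 of 7 erythroid markers, 8 of 14 B cell markers and 6 of 9 class II and dendritic cell markers at 1 CPM or more. Genes named in the text were the 3 targeted genes and 16 core genes, the 8 highest and 8 lowest fold changes per comparison, and up to 4 members per list with the largest change and at least 1 CPM on average. The highest and lowest genes had to reach 10 CPM in the higher group and show no overlap of libraries between the groups, which chance gives for 10% of genes with 3 libraries against 3. Predicted genes, pseudogenes and antigen receptor segments were left out of them. Members named because a count held 5 or fewer genes, or to complete such a count, were chosen after their values were seen. Some genes that these rules would name are not reported here.

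Whether equal replicate numbers pair libraries across genotypes was checked by correlating deviations from the genotype mean over 9149 genes. Between DKO and TKO, the same-number correlations were 0.106, 0.274 and 0.159, all over 0.1, and different-number ones lay between -0.194 and 0.0339. This is a weak hint from the data that the numbers pair these libraries. A different-number pair elsewhere (WT replicate 1 with TKO replicate 3) reached 0.332. The labels state no shared batch or animal beyond a single date. The fit with the replicate number as a block was an alternative.

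The tests were tried on simulated data with counts drawn from the real means and library sizes, with 200 of 16746 genes changed by known folds. For TKO against WT, DKO against WT and TKO against DKO, 54%, 56% and 50% of genes changed 2-fold were called and 100% of those changed 3-fold or 4-fold. Of the unchanged genes, 2 of 15570, 1 of 15588 and 0 of 15539 were called (15, 19 and 9 at the adjusted p alone). A list shifted by 1.5-fold was found in each simulated comparison, and 2 of 34, 1 of 35 and 0 of 35 other lists passed. Simulated genes were drawn independently of one another, and far fewer were changed than the 37.8% called in the real TKO against WT. Rates of false calls and lists under so broad a change, or with correlated genes, were therefore not tried.

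Alternatives were RLE, upper-quartile and no scaling factors beyond library size, DESeq2 1.42.0, limma on the log2 of deposited CPM plus 0.5, other expression filters, other fold and p thresholds, glmTreat, a fit of only the 6 libraries compared, the replicate block, and leaving out each library. A run without ribosomal RNA and mitochondrially encoded genes was added after seeing the data. Overlap between the comparisons with WT was counted again with separate WT libraries for each comparison, a test chosen after seeing the data, in a fit whose spread is pooled over all libraries, so that a lone WT library is assumed to vary like the others. Unchanged groups were also simulated, in 20 draws from the WT means. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No sample column of the tables was left unused.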

Results

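CD4+ T cells of 3 mouse genotypes were compared after culture toward pathogenic Th17 cells, a helper T cell type that makes IL-17 and can drive tissue inflammation. The labels give the genotypes as wild type (WT), mice lacking ORAI2 and ORAI3 (DKO), and mice lacking ORAI1, ORAI2 and ORAI3 (TKO). ORAI proteins form the pore of the calcium release-activated calcium (CRAC) channel, through which T cells take up calcium after their antigen receptor is engaged. The donors were females aged 8 to 12 weeks, and the cells came from spleen and lymph nodes by magnetic enrichment of naive cells. They were activated through CD3 and CD28 for 48 h with IL-6 at 30 ng/ml, IL-23 and IL-1β each at 10 ng/ml, and antibodies that block IL-4 and IFN-γ. Polyadenylated RNA was then sequenced.

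Each genotype had 3 libraries. Per the labels' protocols, the material of 3 biological replicates was pooled within a genotype and then divided into 3 technical replicates, although the titles number the libraries as biological replicates. All p-values therefore measure only the technical spread within a single pool per genotype, and differences between animals of one genotype stay unmeasured. Library totals were 34767536 to 38675797 estimated counts in WT, 31311599 to 33733199 in DKO and 32272317 to 32879094 in TKO. Between 22719 and 23685 genes had a count in a library, and 16746 genes were tested. Libraries of one genotype differed by more than sampling noise, with chi-square values per gene of 2.78 to 2.91 in WT, 3.93 to 8.97 in DKO and 9.52 to 21.7 in TKO, so each was counted separately. The ribosomal RNA gene Rn18s-rs5 took 3.08 to 3.54% of the counts in WT, 1.84 to 2.99% in DKO and 1.02 to 2.12% in TKO. Mitochondrially encoded genes took 2.12 to 2.18% in WT, 1.76 to 1.92% in DKO and 1.17 to 1.44% in TKO. Xist, the RNA that silences an X chromosome in female cells, lay between 699 and 1073 CPM (counts scaled by library size) in every library, and Y-linked genes had 0 to 4 counts per library. Of the 2 members of the sex-linked check that were tested, Xist was not called in any comparison, and its low antisense partner Tsix rose in TKO over WT, from 0.182 to 0.503 CPM. Reads of Xist and Tsix overlap, and how strand was used in counting is not given in the sources used here.

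The targeted genes were examined first. Orai1 (ENSMUSG00000049686) stood at 56.3 ± 1.4 CPM (mean ± SD, n = 3) in WT, 56.6 ± 2.4 in DKO and 5.85 ± 0.39 in TKO. Orai1 fell 9.62-fold in TKO against WT, with a log2 fold change of -3.27 ± 0.06 (SE) and an edgeR adjusted p of 8.19e-16, and differed by 0.01 ± 0.05 between DKO and WT (adjusted p = 0.94). Orai2 (ENSMUSG00000039747) was not reduced in the libraries labelled as lacking it. Orai2 stood at 25.1 ± 0.81 CPM in WT, 35.1 ± 1.0 in the libraries labelled DKO and 154 ± 9.4 in those labelled TKO, so that it rose 6.13-fold in TKO against WT (log2 2.62 ± 0.05, adjusted p = 1.51e-15). Its difference between DKO and WT was 0.48 ± 0.05, under the minimum fold of 2. Orai3 (ENSMUSG00000043964) stood at 15.6 ± 0.98, 12.7 ± 0.87 and 13.6 ± 0.45 CPM in WT, DKO and TKO, with log2 differences from WT of -0.29 ± 0.07 in DKO and -0.19 ± 0.07 in TKO, both under the minimum fold. Gene-level counts do not check a deletion that removes only part of a gene, and the deleted parts are not given in the sources used here. The counts of Orai1 thus match the TKO label, and those of Orai2 and Orai3 check neither genotype. Directions given for DKO and TKO refer to the libraries with these labels. Stim1, whose product senses calcium in the endoplasmic reticulum and opens ORAI channels, stood at 95.8 CPM in WT, 97.5 in DKO and 171 in TKO, a log2 difference of 0.84 ± 0.05 between TKO and WT that did not reach the minimum fold.

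**Figure D1:**
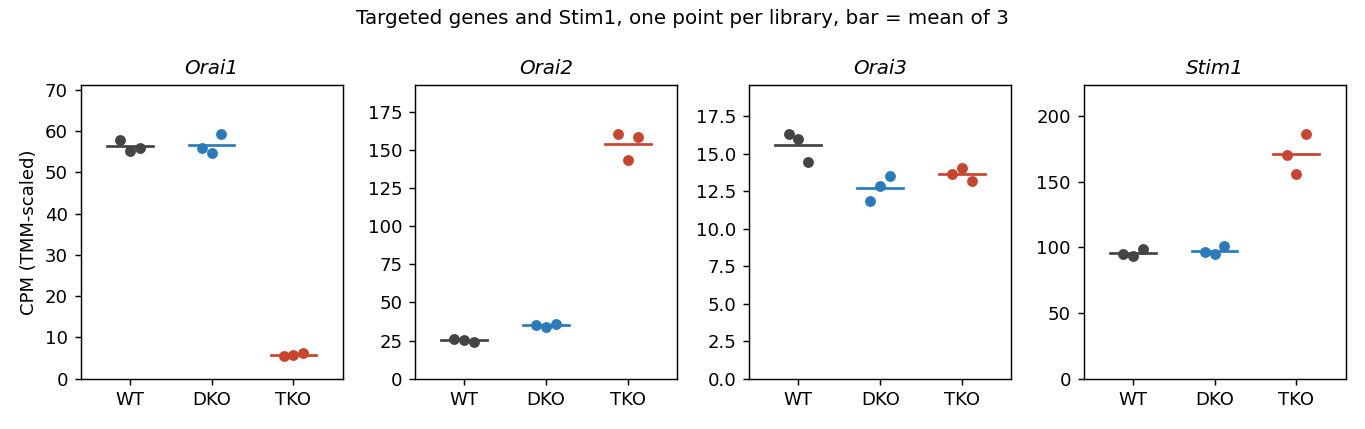
CPM (TMM-scaled, linear axis from 0) of Orai1, Orai2, Orai3 and Stim1 in the 3 libraries of each genotype on the horizontal axis, with a point per library and a bar at the mean of 3. Orai1 averaged 5.85 CPM in TKO against 56.3 in WT and 56.6 in DKO, while Orai2 averaged 154 CPM in TKO against 25.1 in WT and 35.1 in DKO.

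The first comparison asked how cells labelled as lacking all 3 ORAI proteins differ from WT cells under Th17 conditions. TKO cells had far less of several helper T cell cytokine transcripts. Il2, the T cell growth factor, fell 41.1-fold to 2.28 CPM from 93.8 (log2 -5.36 ± 0.11, adjusted p = 2.12e-15). Il17f and Il17a, the Th17 effector cytokines, fell 18.8-fold (log2 -4.24 ± 0.09, 7.64 against 144 CPM) and 5.34-fold (log2 -2.42 ± 0.18, 2.82 ± 0.67 against 15.1 ± 4.1 CPM). Il21 fell 13.2-fold, to 4.57 CPM from 60.5.

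Among 16746 genes, 3374 were higher and 2951 lower in TKO. Over 9149 of these genes, kept for their higher mean level, the first principal component of all libraries held 95.2% of the variance. Il23r, the receptor that responds to IL-23, fell 52.9-fold from 2.28 CPM in WT (log2 -5.73 ± 0.36, adjusted p = 8.04e-10). It had 1 to 2 counts per TKO library, so that its fold is uncertain. Tbx21, the Th1 factor T-bet, fell 17.8-fold (log2 -4.15 ± 0.27), and Foxp3, the regulatory T cell factor, fell 6.32-fold from 16.1 to 2.54 CPM (log2 -2.66 ± 0.14). Csf2, which encodes GM-CSF, and Ifng were low in WT, at 0.742 and 0.716 CPM, and fell by log2 values of -3.01 ± 0.50 and -2.96 ± 0.46. Il22 (log2 0.83 ± 0.32, adjusted p = 0.0264) and Nfatc1, an NFAT factor activated by calcium (log2 -0.73 ± 0.04, 107 against 176 CPM), did not reach the minimum fold.

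The highest rises by the naming rule included Bhlhe41, a circadian and lymphocyte transcriptional repressor (18.7 CPM in TKO against 0 to 4 counts per WT library, so that its fold is uncertain), Thbs1, which encodes the matrix protein thrombospondin 1 (53.2 CPM in TKO, 271-fold), Pianp (32.7 against 0.139 CPM, 232-fold) and the POU factor gene Pou6f1 (164 against 1.04 CPM, 156-fold). Hbb-bs and Hba-a2, which encode globins, rose 198-fold and 155-fold. Lyz2, the lysozyme of myeloid cells, rose 145-fold from 0.0836 to 12.5 CPM. Per WT library, Lyz2 had 2 to 4 counts, Pianp 4 to 6, Hba-a2 4 to 12, and Thbs1 and Hbb-bs 6 to 8. These folds are therefore uncertain too. Olfr533, an olfactory receptor gene, had 3 counts over the WT libraries and 17.8 CPM in TKO, a ratio of 647 with a 95% counting interval of 221 to 3142. Its neighbour Scart2 had nearly the same level in TKO, 17.8 CPM, so reads of the pair may be shared and both are uncertain. The deepest falls were in Scd1, a desaturase that makes monounsaturated fatty acids (0.535 against 127 CPM, 236-fold), Tead1, a partner of YAP (0.295 against 36.8 CPM, 123-fold), Fut4 (96.0-fold), Acsl6 (90.0-fold), Il12rb2, a subunit of the IL-12 receptor (0.455 against 38.9 CPM, 85.1-fold), Sema3b (84.8-fold), Socs2, a suppressor of cytokine signalling (1.98 against 143 CPM, 72.0-fold), and Tgm2, transglutaminase 2 (69.9-fold). Leaving out 1 library moved some folds by over 1.5 times: the log2 values of Csf2 (-3.01) and Tead1 (-6.94) became -4.48 and -7.66 without TKO replicate 2. That of Sema3b (-6.41) became -7.06 without TKO replicate 3. Per TKO library, Sema3b had 2 to 7 counts, Fut4 3 to 6 and Tead1 3 to 18, so that their folds are uncertain.

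**Figure D2:**
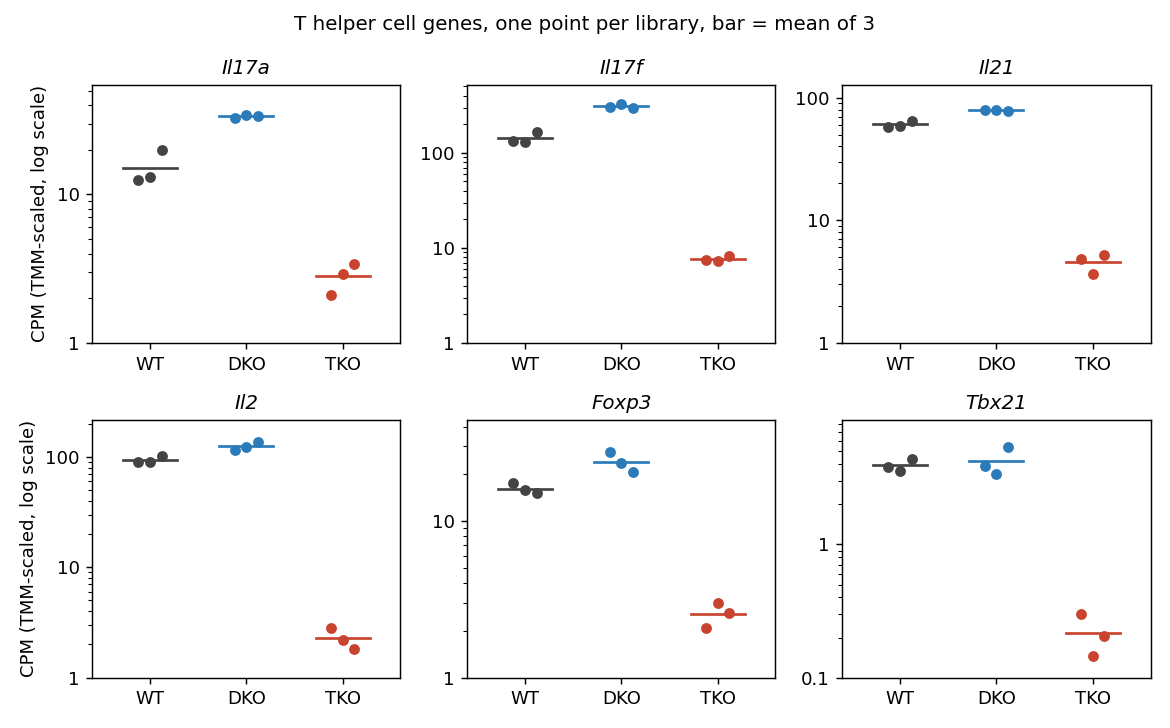
CPM (TMM-scaled, log axis) of Il17a, Il17f, Il21, Il2, Foxp3 and Tbx21 in the 3 libraries of each genotype on the horizontal axis, with a point per library and a bar at the mean of 3. Il17f averaged 144 CPM in WT, 309 in DKO and 7.64 in TKO.

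Of 22 tested members of the pathogenic Th17 signature, 14 fell and 2 rose (Ccl5 and Lgals3) in TKO against WT, with a camera adjusted p of 0.000434 and adjusted p = 0.186 with an estimated correlation. Il3 had 1 count over the TKO libraries, and its WT to TKO ratio was 191 with a 95% counting interval of 34.0 to 7598, while Ccl4, a chemokine of activated T cells, fell with a log2 value of -4.03 ± 0.16. Calcineurin-NFAT and activation genes, which calcium entry turns on, fell in 14 and rose in 6 of 33 (camera adjusted p = 0.0141, and adjusted p = 0.247 with an estimated correlation). Lif, a cytokine of the IL-6 family, fell from 293 to 7.96 CPM (log2 -5.20 ± 0.09), and the chemokine Xcl1 rose to 5.34 from 0.109 CPM (log2 5.56 ± 0.31). The Th17 core list split, with 6 risen and 8 fallen of 25 (camera adjusted p = 0.864, and adjusted p = 0.929 with an estimated correlation). Il24 had 0 counts over the TKO libraries and was at least 97.6-fold lower than in WT, and Il1r1, the IL-1 receptor, fell from 9.52 to 0.621 CPM. Maf (271 against 32.2 CPM), Tmem176a (115 against 30.3 CPM), Tmem176b, Podnl1, Il6st and Il6ra, the last 2 encoding the receptor for IL-6, were the members that rose. Among non-pathogenic Th17 and regulatory cytokine genes, 6 rose and 4 fell of 15 (camera adjusted p = 0.123, and adjusted p = 0.570 with an estimated correlation). Il9 fell from 19.9 to 0.306 CPM, Il10 from 6.12 to 0.139 CPM, and Il1rn with a log2 value of -3.40 ± 0.31, while Ikzf3, the lymphoid factor Aiolos, rose from 22.3 to 334 CPM.

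Genes of other helper lineages changed both ways in TKO against WT. Th1 genes rose in 5 and fell in 5 of 13 (camera adjusted p = 0.688, and adjusted p = 0.869 with an estimated correlation): Nkg7, Eomes and Ccl5 were among those that rose, and Tbx21, Il12rb2, Il18rap, Cxcr3 and Ifng fell. Th2 genes rose in 4 (Gata3, Areg, Crlf2 and Ccr8) and fell in 5 (Il4, Il13, Il24, Ccr4 and Nfil3) of 10 (camera adjusted p = 0.544, and adjusted p = 0.649 with an estimated correlation), with the chemokine receptor Ccr4 at 56.1 against 218 CPM. In the regulatory T cell list, 3 rose (Itgae, Ikzf4 and Capg) and 4 fell (Il2ra, Foxp3, Lrrc32 and Ctla4) of 14 (camera adjusted p = 0.864, and adjusted p = 0.905 with an estimated correlation). Il2ra, the IL-2 receptor chain CD25, fell from 1417 to 132 CPM (log2 -3.42 ± 0.04), and Itgae, the integrin CD103, rose from 0.924 to 23.5 CPM (log2 4.67 ± 0.17). Naive and quiescent T cell genes rose in 19 of 26 and fell in 0, with a camera adjusted p of 2.54e-09 and adjusted p = 0.186 with an estimated correlation. Klf2, a quiescence factor, rose from 4.09 to 224 CPM (log2 5.77 ± 0.08), and Pik3ip1, an inhibitor of PI3 kinase, from 4.39 to 95.5 CPM. Anergy and exhaustion genes rose in 8 and fell in 2 (Pdcd1 and Ctla4) of 19 (camera adjusted p = 0.411, and adjusted p = 0.679 with an estimated correlation). Tox2 rose from 0.965 to 55.1 CPM, and Dgka, a kinase that removes diacylglycerol, from 150 to 558 CPM.

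Most lists of metabolism and growth genes lay lower in TKO than in WT. Glycolysis genes fell in 15 and rose in 1 (Pfkfb4) of 22 (camera adjusted p = 2.81e-08, and adjusted p = 0.187 with an estimated correlation), with the hexokinase Hk2 at 36.0 against 374 CPM and the lactate transporter Slc16a3 at 12.8 against 241 CPM. Fatty acid synthesis genes fell in 9 of 14 and cholesterol synthesis genes in 15 of 25, with 0 risen in either (camera adjusted p = 3.79e-06 and 1.75e-07, and adjusted p = 0.186 and 0.194 with an estimated correlation). Scd2 fell from 1875 to 74.2 CPM, Fads2 from 79.3 to 3.67 CPM, and the cholesterol enzymes Lss and Idi1 with log2 values of -2.04 and -2.01. Genes for nuclear-encoded oxidative phosphorylation fell in 7 of 46 and rose in 0 (camera adjusted p = 2.54e-09, and adjusted p = 0.186 with an estimated correlation), led by Cycs, cytochrome c, at log2 -2.22 ± 0.14. MYC and ribosome biogenesis genes fell in 22 of 26 and rose in 0 (camera adjusted p = 3.78e-11, and adjusted p = 0.186 with an estimated correlation), with the spermidine synthase Srm at 66.0 against 372 CPM and the nucleolar genes Npm1 and Ncl at log2 -2.30 and -2.07. Cell cycle genes fell in 13 of 28 for S phase and in 19 of 26 for G2 and M phase, with 0 risen (camera adjusted p = 2.04e-09 and 4.17e-10, and adjusted p = 0.204 and 0.186 with an estimated correlation). Ccne2, cyclin E2, and Ccnb1, cyclin B1, had log2 values of -2.51 and -2.07. ATF4 and amino acid response genes fell in 16 and rose in 1 (Ddit3) of 26 (camera adjusted p = 2.15e-05, and adjusted p = 0.186 with an estimated correlation), with the asparagine synthetase Asns at 6.49 against 49.2 CPM. Cytosolic ribosomal protein genes fell in 3 (Rpl10, Rpl12 and Rpl35) of 75 and rose in 0 (camera adjusted p = 0.426, and adjusted p = 0.902 with an estimated correlation). In these same libraries, mitochondrially encoded genes fell in 7 of 15 and rose in 0 (camera adjusted p = 9.58e-05, and adjusted p = 0.307 with an estimated correlation), with mt-Nd3 at log2 -1.63.

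Among stress lists, hypoxia and HIF1A targets fell in 12 and rose in 1 (Pfkfb4) of 20 (camera adjusted p = 0.00216, and adjusted p = 0.186 with an estimated correlation), with Ldha, lactate dehydrogenase A, at 721 against 2925 CPM. The p53 targets fell in 10 and rose in 3 (Bbc3, Fas and Trp53inp1) of 20 (camera adjusted p = 0.00621, and adjusted p = 0.186 with an estimated correlation), and Cdkn1a, the cell cycle inhibitor p21, fell from 131 to 21.3 CPM. Heat shock and dissociation stress genes fell in 7 and rose in 1 (Fos) of 15 (camera adjusted p = 0.0377, and adjusted p = 0.186 with an estimated correlation), with the chaperonin genes Hspd1 and Hspe1 at log2 -2.84 and -2.22. Genes of the endoplasmic reticulum unfolded protein response fell in 4 (Hsp90b1, Canx, Sdf2l1 and Manf) and rose in 1 (Derl3) of 20 (camera adjusted p = 0.0582, and adjusted p = 0.186 with an estimated correlation). Apoptosis regulators rose in 5 (among them Bmf, Birc3, Fas and Bbc3) and fell in 2 (Bid and Tnfrsf10b) of 20 (camera adjusted p = 0.864, and adjusted p = 0.902 with an estimated correlation).

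In lists of signalling and migration genes, more members rose than fell in TKO against WT. SMAD3 and TGF-beta response genes rose in 9 and fell in 3 (among them Itgb8 and Furin) of 14 (camera adjusted p = 0.00164, and adjusted p = 0.204 with an estimated correlation), with the receptor gene Tgfbr2 at 707 against 84.9 CPM and its feedback inhibitor Smad7 at 216 against 27.8 CPM. Chemokine receptor and adhesion genes rose in 12 and fell in 3 (Itgb1, Ccr4 and Cxcr3) of 20 (camera adjusted p = 0.0127, and adjusted p = 0.194 with an estimated correlation), with S1pr1, which lets T cells leave lymph nodes, at 224 against 21.5 CPM. Interferon response genes rose in 10 and fell in 2 (Bst2 and Igtp) of 23 (camera adjusted p = 0.0960, and adjusted p = 0.194 with an estimated correlation). STAT3 and SOCS response genes rose in 5 (Il6st, Bcl6, Il6ra, Socs3 and Bcl3) and fell in 3 (Pim1, Cebpb and Osm) of 17 (camera adjusted p = 0.927, and adjusted p = 0.966 with an estimated correlation). CRAC channel and calcium handling genes rose in 8 and fell in 3 (Orai1, Atp2b4 and Atp2a2) of 25 (camera adjusted p = 0.0826, and adjusted p = 0.194 with an estimated correlation), with the channel regulator Cracr2a at 51.9 against 9.58 CPM and the calcium release receptor Itpr2 at 167 against 35.1 CPM.

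Markers of other cell types rose in the same TKO libraries, beside each group above. Macrophage, monocyte and neutrophil markers rose in all 10 tested members (camera adjusted p = 0.00216, and adjusted p = 0.186 with an estimated correlation), with the integrin Itgam at 10.0 against 0.12 CPM and the protease Ctss at 140 against 37.8 CPM. S100a9 had 1 count over the WT libraries, and its TKO to WT ratio was 362 with a 95% counting interval of 64.4 to 14322, while S100a8 had 0 counts in WT and was at least 39.5-fold higher in TKO. Erythroid and platelet markers rose in 6 and fell in 0 of 7 (camera adjusted p = 0.00730, and adjusted p = 0.186 with an estimated correlation). Among them, Hba-a1 and Hba-a2 are near-identical to each other, as are Hbb-bs and Hbb-bt, so the split of reads within each pair is uncertain. The summed CPM of the myeloid list was 178 in TKO and 41.1 in WT, and that of the erythroid list 110 and 2.02. Of 18 listed myeloid and 13 listed erythroid genes, 10 and 7 were tested, and 2 and 0 of those reached 1 CPM in WT. Markers scarce in WT can pass the expression filter through TKO alone, so these counts, sums and camera p-values are partly set by the filter. Dendritic cell and class II genes rose in 5 (Ciita, Cd74, Fscn1, H2-Aa and H2-Eb1) and fell in 1 (Flt3) of 9 (camera adjusted p = 0.136, and adjusted p = 0.448 with an estimated correlation), with the invariant chain Cd74 at 405 against 75.5 CPM. H2-Eb1 had a log2 value of 1.06 that became 0.98, under the minimum fold, with limma on the deposited CPM. B cell and plasma cell genes rose in 3 (Cd79a, Cd79b and Iglc1) and fell in 6 of 14 (camera adjusted p = 0.544, and adjusted p = 0.649 with an estimated correlation), with the B cell factors Ebf1 and Pax5 at log2 -3.97 and -2.83. CD8 T cell genes rose in 3 of 6 and fell in 0 (camera adjusted p = 0.132, and adjusted p = 0.227 with an estimated correlation): Eomes, the perforin gene Prf1, and Gzmk, which had 0 counts in WT and was at least 78.5-fold higher. NK and innate lymphoid genes rose in 2 (Tyrobp and Fcer1g) of 3, and gamma-delta T and NKT cell genes in 2 (Trdc and Trgc1) of 6, with 0 fallen (camera adjusted p = 0.411 and 0.336, and adjusted p = 0.506 and 0.417 with an estimated correlation). Stromal and endothelial genes rose in 3 (Madcam1, Pecam1 and Col1a1) and fell in 1 (Lum, at 0 counts in TKO and at least 55.8-fold lower) of 5 (camera adjusted p = 0.411, and adjusted p = 0.570 with an estimated correlation).

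In this comparison 19 of 37 lists passed camera's adjusted threshold with the preset correlation and 0 with an estimated correlation, while 36 passed fry, which asks whether a list's genes move one way without comparing them with other genes. The counts of members risen or fallen adjusted over the list alone equalled those over all genes tested in every list, here and in TKO against DKO. Median, mean and test differed in sign in the Th17 core, apoptosis and STAT3 lists.

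**Figure D3:**
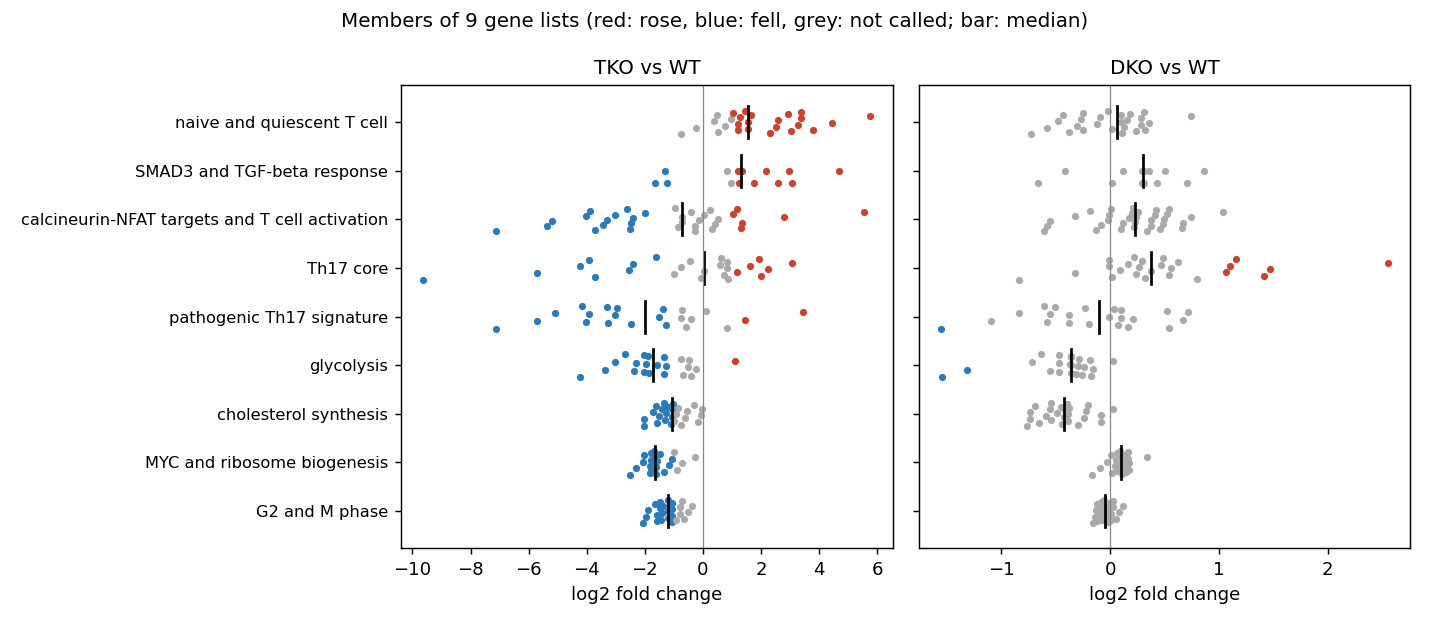
Log2 fold change (horizontal axis, scales differing between panels) of each tested member of 9 gene lists on the vertical axis, in TKO against WT and in DKO against WT; points are genes, red where the gene rose, blue where it fell and grey where it was not called, and bars are list medians. MYC and ribosome biogenesis genes fell in 22 of 26 in TKO and in 0 in DKO, and Il24 is drawn at its fitted value although it had 0 counts in TKO.

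The second comparison asked how cells labelled as lacking ORAI2 and ORAI3 differ from WT cells. Their Orai1 lay at its WT level. DKO cells had more Il17f and Il17a transcript than WT cells. Il17f rose 2.15-fold, from 144 to 309 CPM (log2 1.10 ± 0.07, adjusted p = 1.15e-07), and Il17a rose 2.23-fold, from 15.1 to 33.7 CPM (log2 1.16 ± 0.14, adjusted p = 3.32e-05). Ccl20, a chemokine that Th17 cells make, rose 5.89-fold from 1.97 to 11.6 CPM (log2 2.56 ± 0.14), and the cytokine genes Il9 and Il10 rose 3.46-fold to 69.0 CPM and 2.79-fold to 17.1 CPM. Scd1 fell 7.41-fold, from 127 to 17.1 CPM (log2 -2.89 ± 0.12), and Ccl22, a chemokine that draws CCR4-bearing cells, fell 9.71-fold to 2.32 CPM from 22.5 (log2 -3.28 ± 0.12, adjusted p = 3.3e-10).

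In all, 135 genes were higher and 141 lower in DKO, or 1.65% of those tested. The other genes with the highest rises by the naming rule were Cd5l, a regulator of lipid synthesis in Th17 cells (3.52-fold, 26.4 against 7.52 CPM), Cyp1a1, a target of the aryl hydrocarbon receptor (2.99-fold), the scavenger receptor gene Stab1 (2.98-fold), Apol9b (2.88-fold), whose reads may be shared with its near-identical copy Apol9a, and Tmem176a (2.77-fold, 83.9 against 30.3 CPM). The other deepest falls were in Wdfy1 (3.78-fold), the desaturase gene Fads2 (3.65-fold, 21.7 against 79.3 CPM), the mitophagy gene Bnip3 (3.43-fold), the granzyme gene Gzmb (2.94-fold, 4.50 against 13.2 CPM), the cholesterol exporter gene Abca1 (2.59-fold) and Gvin2 (2.55-fold), whose reads may be shared with copies. Many core genes stayed under the minimum fold: Il2 (log2 0.41, adjusted p = 0.000833), Il21 (0.38, adjusted p = 0.000552), Foxp3 (0.57, adjusted p = 0.00156), Il23r (-0.84, adjusted p = 0.011), Nfatc1 (0.20), Tbx21 (0.10), Csf2 (0.10), Ifng (-0.19), Il22 (0.17) and Stim1 (0.03).

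The Th17 core and non-pathogenic Th17 lists lay higher in DKO than in WT. The Th17 core list rose in 6 of 25 (Il17a, Il17f, Ccl20, Tmem176a, Tmem176b and Maf) and fell in 0, with a camera adjusted p of 3.43e-15 and adjusted p = 0.0275 with an estimated correlation. Non-pathogenic Th17 and regulatory cytokine genes rose in 5 of 15 (Il1rn, Cd5l, Il9, Il10 and Maf) and fell in 0 (camera adjusted p = 8.01e-13, and adjusted p = 0.0577 with an estimated correlation), with Il1rn, the IL-1 receptor antagonist, at 5.20 against 1.29 CPM. In the pathogenic Th17 signature 1 of 22 fell (Gzmb) and 0 rose (camera adjusted p = 0.103, and adjusted p = 0.304 with an estimated correlation). Calcineurin-NFAT and activation genes had 0 of 33 called, with Egr2 at log2 0.74, Ccl4 at 0.67 and Tnf at 0.66 under the minimum fold. As a list they lay higher than other genes (camera adjusted p = 0.000114, and adjusted p = 0.146 with an estimated correlation). SMAD3 and TGF-beta response genes also had 0 of 14 called and lay higher as a list, with Pmepa1 at log2 0.86 (camera adjusted p = 9.40e-09, and adjusted p = 0.0673 with an estimated correlation). MYC and ribosome biogenesis genes and p53 targets had 0 called and lay slightly higher (camera adjusted p = 9.77e-05 and 0.00910, and adjusted p = 0.328 and 0.140 with an estimated correlation).

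Lists of lipid synthesis, glycolysis and hypoxia genes lay lower in DKO than in WT by camera with the preset correlation, with few members called. Fatty acid synthesis genes fell in 3 of 14 (Scd1, Scd2 and Fads2) and rose in 0 (camera adjusted p = 2.37e-15, and adjusted p = 0.0514 with an estimated correlation), with Scd2 at 762 against 1875 CPM. Cholesterol synthesis genes had 0 of 25 called but 21 lower past the adjusted p alone, with Pmvk at log2 -0.77 and Fdps and Lss at -0.74 (camera adjusted p = 1.54e-23, and adjusted p = 0.0534 with an estimated correlation). Glycolysis genes fell in 2 of 22 and rose in 0 (camera adjusted p = 1.54e-23, and adjusted p = 0.0514 with an estimated correlation): the aldolase gene Aldoc at log2 -1.54 and Slc16a3 at 97.1 against 241 CPM. Hypoxia and HIF1A targets fell in 2 of 20 (P4ha2 and Bnip3) and rose in 0, with a camera adjusted p of 9.79e-16 and adjusted p = 0.0221 with an estimated correlation. ATF4 and amino acid response genes fell in 3 of 26 (Vldlr, Chac1 and Trib3) and rose in 0 (camera adjusted p = 0.177, and adjusted p = 0.707 with an estimated correlation). Trib3, at log2 -1.11, fell just short of the minimum fold with limma on the deposited CPM. Interferon response genes rose in 1 of 23 (Cxcl10, log2 1.80 ± 0.20) and fell in 0, yet lay lower as a list (camera adjusted p = 0.000960, and adjusted p = 0.0514 with an estimated correlation).

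Several lists with members called in TKO had 0 called in DKO against WT: CRAC channel and calcium handling (camera adjusted p = 0.361), naive and quiescent T cell (0.543), oxidative phosphorylation (0.341), S phase (0.543), and G2 and M phase (0.0899). Anergy and exhaustion, Th2, regulatory T cell, apoptosis, chemokine receptor, unfolded protein response, heat shock and ribosomal protein lists also had 0 called, with camera adjusted p from 0.103 to 0.766. The STAT3 and SOCS list fell in 1 of 17 (Fgl2, camera adjusted p = 0.394) and the Th1 list in 1 of 13 (Eomes, camera adjusted p = 0.0582). Eomes, a factor of cytotoxic T cells, had a log2 value of -1.48 and an adjusted p of 0.0142. The adjusted p became 0.0783 without WT replicate 3, 0.0661 without DKO replicate 2 and 0.0679 without DKO replicate 3. Its log2 value was then -1.15, -1.34 and -1.24. With limma on the deposited CPM it was -0.68, under the minimum fold.

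Of the markers of other cell types, those of B cells fell in the same DKO libraries. B cell and plasma cell genes fell in 9 of 14 and rose in 0, with a camera adjusted p of 2.00e-09 and adjusted p = 0.0221 with an estimated correlation. The IgE receptor gene Fcer2a stood at 0.616 against 4.20 CPM, and Pax5 had a log2 value of -2.16 ± 0.23. Dendritic cell and class II genes fell in 4 of 9 (Fscn1, H2-Ab1, H2-Aa and Flt3) and in 5 when adjusted over the list alone (camera adjusted p = 0.00297, and adjusted p = 0.219 with an estimated correlation). H2-Aa, at log2 -1.02, became -0.97 without WT replicate 1 and -0.80 without DKO replicate 2. CD8 T cell genes fell in 2 of 6 (Eomes and Prf1, camera adjusted p = 0.177). Prf1 had a log2 value of -1.15 and an adjusted p of 0.0186. The adjusted p became 0.0827 without WT replicate 3, 0.0902 without DKO replicate 1 and 0.0718 without DKO replicate 2. Its log2 value was then -1.01, -0.94 and -1.07, and with limma on the deposited CPM it was -0.57. Macrophage, monocyte and neutrophil markers fell in 2 of 10 (Cybb and Mpeg1, camera adjusted p = 0.902), gamma-delta T and NKT markers in 1 of 6 (Blk, camera adjusted p = 0.609), and erythroid, NK and stromal markers in 0 (camera adjusted p = 0.793, 0.793 and 0.341), with 1 stromal gene fallen when adjusted over the list alone. Mpeg1 had 1 count over the DKO libraries, and its WT to DKO ratio was 13.2 with a 95% counting interval of 2.03 to 555. Mitochondrially encoded genes had 0 of 15 called and lay lower as a list, with mt-Atp6 at log2 -0.53 (camera adjusted p = 5.08e-08, and adjusted p = 0.265 with an estimated correlation). For DKO against WT, 14 of 37 lists passed camera's adjusted threshold and 3 did with an estimated correlation, namely Th17 core, B cell and hypoxia genes, and 20 passed fry. Median, mean and test differed in sign in the Th2, naive, anergy, S phase, STAT3, chemokine receptor, macrophage and gamma-delta T cell lists, none of which passed camera.

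The third comparison set TKO against DKO, whose labels differ by the loss of ORAI1. Cytokine transcripts were again far lower in TKO. Il2 fell 54.5-fold (log2 -5.77 ± 0.11), Il17f 40.4-fold (log2 -5.34 ± 0.09), Il21 17.2-fold and Il17a 11.9-fold. Il9 and Il10 fell 223-fold (0.306 against 69.0 CPM) and 120-fold (0.139 against 17.1 CPM). Orai1 fell with a log2 value of -3.27 ± 0.06, Orai2 rose by 2.13 ± 0.05 on that scale, and Orai3 differed by 0.10 ± 0.07 (adjusted p = 0.239).

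Of all genes tested, 3380 were higher and 2779 lower in TKO than in DKO. Il23r fell 29.7-fold (1 to 2 counts per TKO library, fold uncertain). Tbx21 fell 19.1-fold, Foxp3 9.39-fold, Csf2 8.64-fold and Ifng 6.81-fold (log2 -2.77, and -0.89, under the minimum fold, with limma on the deposited CPM). Il22 (log2 0.66, adjusted p = 0.0697), Stim1 (0.81) and Nfatc1 (-0.93) were not called. The highest rises were in Bhlhe41 (0 to 4 counts per DKO library, fold uncertain), Olfr533, Hbb-bs (239-fold), Scart2 (205-fold), Pou6f1 (146-fold), Hba-a1 (129-fold), Hba-a2 (111-fold) and Lyz2 (105-fold). Per DKO library, Olfr533 had 1 to 3 counts, Scart2 1 to 5, Lyz2 1 to 8 and Hba-a1 0 to 8. Hbb-bs had 4 to 7 and Hba-a2 5 to 14, so that all these folds are uncertain too. Besides Il9, Il10 and Il2, the deepest falls were in Tead1 (139-fold), Fut4 (83.6-fold), the activin gene Inhba (80.2-fold), Socs2 (70.0-fold) and the leukotriene receptor gene Cysltr1 (52.1-fold). Per TKO library, Il10 had 2 to 6 counts, Inhba 2 to 10, Fut4 3 to 6 and Tead1 3 to 18, so that these folds are uncertain. The log2 values of Csf2 (-3.11) and Tead1 (-7.12) became -4.59 and -7.84 without TKO replicate 2. That of Scart2 (7.68) became 8.42 without DKO replicate 2, and that of Lyz2 (6.72) became 7.95 without DKO replicate 1. Il24 was at least 135-fold lower in TKO than in DKO.

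Naive and quiescent T cell genes rose in 19 of 26 and fell in 0 in TKO against DKO (camera adjusted p = 8.25e-10, and adjusted p = 0.164 with an estimated correlation). MYC and ribosome biogenesis genes fell in 24 of 26, S phase genes in 13 of 28 and G2 and M phase genes in 19 of 26, with 0 risen (camera adjusted p = 7.66e-12, 8.25e-10 and 4.10e-10, and adjusted p = 0.164, 0.210 and 0.210 with an estimated correlation). Within the first of these, Myc itself had a log2 value that fell short of the minimum fold with library size as the only scaling (-0.98). The pathogenic Th17 signature fell in 13 and rose in 2 (Ccl5 and Lgals3) of 22, and calcineurin-NFAT genes fell in 16 and rose in 3 (Xcl1, Tnfsf8 and Egr1) of 33 (camera adjusted p = 0.00225 and 0.00427, and adjusted p = 0.164 and 0.210 with an estimated correlation). The Th17 core list fell in 10 and rose in 4 (Podnl1, Il6st, Il6ra and Maf) of 25 (camera adjusted p = 0.400, and adjusted p = 0.669 with an estimated correlation). Glycolysis genes fell in 12 and rose in 1 of 22, fatty acid synthesis genes fell in 8 of 14 and cholesterol synthesis genes in 6 of 25 (camera adjusted p = 7.25e-06, 0.000352 and 0.000103, and adjusted p = 0.210, 0.210 and 0.283 with an estimated correlation). Mitochondrially encoded genes fell in 3 (mt-Rnr2, mt-Nd2 and mt-Nd3) of 15, with all 15 lower past the adjusted p alone, and heat shock genes fell in 7 and rose in 1 (Fos) of 15 (camera adjusted p = 0.00107 and 0.0197, and adjusted p = 0.357 and 0.167 with an estimated correlation). Interferon response genes rose in 12 and fell in 2 (Cxcl10 and Bst2) of 23 (camera adjusted p = 0.0197, and adjusted p = 0.164 with an estimated correlation). Markers of other cell types rose alongside: myeloid markers in 9 of 10, erythroid markers in 5 of 7, class II and dendritic cell genes in 7 of 9 and B cell genes in 7 of 14, the last with Ebf1 fallen (camera adjusted p = 0.00225, 0.00803, 0.0111 and 0.185, and adjusted p = 0.164, 0.164, 0.210 and 0.309 with an estimated correlation). Here too, scarce markers can pass the expression filter through TKO alone, which partly sets the myeloid and erythroid values. H2-Eb1 became 0.96 without DKO replicate 2 and 0.98 without TKO replicate 3, and Igkc became 0.98 without TKO replicate 3. In all, 20 of 37 lists passed camera's adjusted threshold, 0 with an estimated correlation, and 36 passed fry. Median, mean and test differed in sign in the non-pathogenic Th17, apoptosis and STAT3 lists.

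Both knockouts were then set side by side against WT. In DKO and TKO alike, 69 genes rose and 75 fell, 144 in all, where independent lists of these sizes would share 27.2 and 24.8. Pianp rose in both (0.139 CPM in WT, 9.78 in DKO and 32.7 in TKO), as did Vcam1, an adhesion molecule gene (log2 2.37 in DKO and 3.79 in TKO), and Cyp1a1 (1.58 and 5.17). Ccl22 (log2 -3.28 and -5.28), Scd1 and Fcer2a fell in both. Another 63 genes changed in opposite directions, 36 of them higher in DKO and lower in TKO, where independent lists would give 23.8, and 27 the other way, where they would give 28.4. Il17a, Il17f, Il9, Il10, Ccl20, Il1rn and Cd5l were among the genes that were higher in DKO and lower in TKO, as was Inhba at log2 1.13 and -5.19. Abcg1, a cholesterol exporter gene, went the other way at -1.26 and 1.14. Pianp, Vcam1, Inhba and Abcg1 were singled out here after their values were seen. Both comparisons use the same 3 WT libraries and so share their chance values. With 1 WT library set against one knockout and the other two against the other, in each of 6 ways, 84 to 120 genes changed in the same direction, where independent lists would share 31.7 to 43.6. Those changed in opposite directions then numbered 30 to 54, where independent lists would give 31.4 to 43.8. In 1 of the 6 ways they were fewer (30 against 32.4). Part of the excess with all WT libraries may come from the shared controls. Without DKO replicate 1, the number of genes changed in opposite directions was 41.

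**Figure D4:**
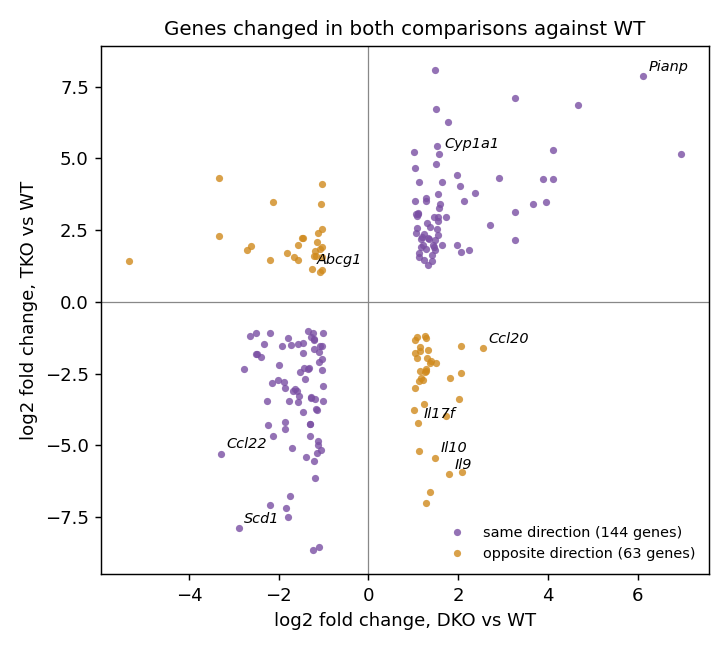
Log2 fold change in DKO against WT (horizontal axis) and in TKO against WT (vertical axis) of the 207 genes changed in both, with a point per gene. The 144 purple points changed in the same direction and the 63 orange points in opposite directions, the latter including Il17f, Il9, Il10 and Ccl20.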

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

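The run without ribosomal RNA and mitochondrially encoded genes was chosen after seeing the data; the other alternatives were fixed earlier. Over 511 fold changes of named genes and 11726 alternative values of them, 11448 kept their direction and side of the threshold, 40 lost the call, 208 gained it, 30 without a call changed sign and 0 reversed. No scaling moved the median of all genes by over 0.0909 on the log2 scale or the share of higher genes by over 10 percentage points. Each scaling is relative to a library's own counts, so a change in the amount of RNA per cell stays unmeasured.

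With no minimum fold, 6811 genes were higher and 6713 lower in TKO against WT, 1315 and 1195 in DKO against WT, and 6850 and 6630 in TKO against DKO; 1488 changed the same way in both comparisons with WT and 752 oppositely, and Orai2 (0.48) and Orai3 (-0.29) in DKO and Orai3 (-0.19) in TKO against WT were then called. A minimum fold of 1.5 gave 4699 lower genes in TKO against WT, 277 higher and 310 lower in DKO, 4526 lower in TKO against DKO, 330 shared and 142 opposite. Limma on the deposited CPM gave 1894 lower genes in TKO against WT, 59 higher and 52 lower in DKO, 1792 lower in TKO against DKO, 60 shared and 20 opposite. In DKO against WT, glmTreat against 1.5-fold gave 81 higher and 77 lower (87 shared, 31 opposite), and an adjusted p under 0.001 gave 70 and 57 (67 shared, 27 opposite). With other thresholds the change follows from the threshold; for limma the cause was not tested. The difference of Orai1 between DKO and WT, near 0, was -0.00176 with upper-quartile factors and between -0.0229 and 0.0313 as each library was left out.

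Leaving out each library in turn gave 3394 to 3568 higher and 2992 to 3125 lower genes in TKO against WT, 108 to 159 and 109 to 167 in DKO against WT, 3383 to 3541 and 2765 to 2952 in TKO against DKO, 117 to 168 shared and 41 to 70 opposite. The run without ribosomal RNA and mitochondrially encoded genes gave 3366 and 2948, 135 and 141, and 3373 and 2783. The lists past camera went from 19, 14 and 20 to 0, 3 and 0 with an estimated correlation, and 36, 20 and 36 passed fry.

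With a paired fit that takes the replicate number as a block, 3364 genes were higher and 2962 lower in TKO against WT, 124 and 136 in DKO against WT, and 3364 and 2779 in TKO against DKO; the block changed no list call and no count by over 1.5 times. Same-number correlations were 0.000520, 0.102 and -0.0921 between WT and DKO and -0.192, 0.178 and -0.176 between WT and TKO, so those libraries share only a number. At 31311599 counts or more per library, genes under 0.1 CPM have few counts per library, and single pools limit every comparison.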

Other observations

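The gene groups of this opening paragraph and the tests of T cell share, of separate WT libraries, of DNA from another strain and of Orai2 were chosen only after the results were seen. Targets of the aryl hydrocarbon receptor, a sensor of small aromatic compounds that shapes Th17 cells, rose in 3 of 7 tested genes in DKO and in 4 in TKO against WT, with 0 fallen. Cyp1a1 rose from 4.53 CPM in WT to 13.6 in DKO and 163 in TKO (log2 1.58 ± 0.12 and 5.17 ± 0.10), and Ahrr, the receptor's repressor, from 3.28 to 7.75 and 17.0 CPM. Cyp1b1 rose in DKO alone by the threshold, at 2.23, 8.80 and 3.40 CPM, and Ugt1a6a and Tiparp in TKO alone. Tiparp had a log2 value of 1.03 that became 0.98 without WT replicate 1 and 0.97 without TKO replicate 1. Ahr itself stood at 74.2, 129 and 122 CPM, under the minimum fold. Targets of LXR, a receptor for oxidised sterols, fell in 4 of 10 in DKO (Abca1, Abcg1, Scd1 and Scd2) and rose in 0. In TKO 4 of them rose (Abcg1, Mylip, Nr1h3 and Smpdl3a) and 2 fell (Scd1 and Scd2). Of 12 targets of IL-2 and STAT5, 0 reached the minimum fold in DKO, while in TKO 6 fell (Socs2, Il2ra, Lif, Lta, Osm and Pim1) and 1 rose (Socs3). Cish, at log2 -0.47, was not called.

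Markers of myeloid and red cells were far higher in TKO than in WT, after magnetic enrichment of naive CD4+ T cells that would remove such cells. A lower share of T cells should raise the markers of every other cell type alike. All list members in the count table were used, tested or not and with 1 count added. The median log2 ratio of 30 myeloid and red cell genes was 3.03 (quartiles 1.47 and 5.62). That of 16 B cell genes was 0.19 (quartiles -1.54 and 1.11), a difference of 2.84. B cell genes, however, also lay lower as a list in DKO than in WT (camera adjusted p = 2.00e-09). More of them rose than fell in TKO against DKO. The WT pool may thus hold more B cell RNA, so this contrast with WT cannot decide whether T cells made up a lower share in TKO. On a second list of neutrophil genes, 12 of 13 countable members (92.3%) were at least 2-fold higher on average with every TKO library above every WT library, with Ngp at 2.95, Mmp9 at 1.53 and Ltf at 1.42 CPM, none of them at 1 CPM in WT, so carried-over neutrophils may account for part of the pattern. Second lists gave 40.0% for red cell precursors (4 of 10, 1 lower) and 44.4% for macrophages (4 of 9, 1 lower), and these cannot be told apart from T cell expression, since the shares lie between the limits set for and against carry-over and the members that did not rise include abundant ones that would hide a small share (Fech, Slc25a37 and Axl at 34.8, 58.4 and 110 CPM in WT) and scarce ones (Klf1, Hemgn and Tspan33 at 0.239, 1.66 and 0.679 CPM in WT and 0.138, 1.41 and 0.138 in TKO). A peculiarity of the single TKO or WT pool, and a change of these genes in T cells through loss of ORAI1, stay open and untested.

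Orai2 counts were higher in the libraries labelled as lacking ORAI2. If reads of Orai1 had only moved to its relatives, the summed CPM of the 3 Orai genes would have stayed level, but it went from 97.0 ± 2.76 in WT to 174 ± 9.04 in TKO, a ratio of 1.79. Reads spilling from neighbours would need a like gain next door, but the largest gain among the 2 nearest tested genes on each side was 8.79% of that of Orai2 (Alkbh4, 11.3 against 129 CPM), while Lrwd1, Prkrip1 and Sh2b2 had log2 values of -0.24, -0.79 and -2.33. What stays open includes a transcript from a part of the locus that was not deleted, and whether the labels hold for Orai2, since the deleted part is not given in the sources used here. Both labels state the loss of ORAI2, yet Orai2 stood at 35.1 CPM in DKO and 154 in TKO, 4.39-fold higher. A remaining transcript alone would leave this difference unexplained, and its cause was not tested.

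Genes changed the same way in DKO and TKO numbered 144, an excess of 92.0 over independent lists. Simulated unchanged groups called 0 or 1 gene per comparison, so their shared count of 0 decides nothing. Across genes, the log2 fold changes of both comparisons had a covariance of 0.126, above the simulated highest of 0.0189. Their correlation of 0.215 lay below the simulated mean of 0.482, but these correlations cannot be compared. The simulated groups held no changed genes, whereas 37.8% of genes were called in TKO against WT. Such broad change in one comparison can lower a correlation whether or not the overlap is real, so the correlation decides nothing here. Chance differences of the shared WT libraries should leave little excess once each comparison has its own WT libraries, but the lowest excess in 6 such assignments was 52.0, or 56.5% of that with shared libraries, so chance alone does not account for the overlap. DNA of another strain around the targeted loci should gather these genes near Orai2 and Orai3, but 4 of the 141 that could be placed (2.84%, exact 95% interval 0.778 to 7.10%) lay among the 100 tested genes on each side, among them Syce1, Cldn4 and Bnip3, where 3.43 would by chance (Fisher's exact test, two-sided p = 0.589). A peculiarity of the single WT pool, which both comparisons share, may still produce the overlap, and a common effect of losing ORAI2 and ORAI3, as both labels state, stays untested.

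Each comparison's 6 libraries can be split into groups of 3 in only 10 ways, too few for a share under 0.05. In fits of those 6 libraries, the real split gave 6215 changed genes in TKO against WT, 293 in DKO against WT and 5940 in TKO against DKO, it was the only 1 of 10 to reach its count each time, and the highest of the other splits gave 0. For lists past camera with the preset correlation, the real split gave 19, 14 and 20 and the highest of the others 18, 13 and 18. Every other split mixes both genotypes in each group. A genotype difference then adds to the spread within groups, so the lack of calls follows from the mixing. Part of that difference also stays between the mixed groups, so lists can still pass. The splits therefore decide nothing about chance, and single pools leave differences between animals unmeasured.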
